A study of Mus musculus with 5 samples.

How the data were processed

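RNA sequencing libraries from RAW264.7 cells, a mouse macrophage-like line, were compared across 3 groups. There was 1 library from cells with vector, 2 from cells with LPS at 0.5 mg/mL, and 2 from cells with LPS and arctigenin at 1 μM, with the doses as labelled. The labels do not say what the vector treatment contained, so it is not read here as the solvent of arctigenin. The deposited table held an estimated count (an expected count that need not be whole) for each RefSeq transcript and library. Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq were used with mouse build mm9, per the submitters' processing notes, which give neither versions nor the order of the tools. The tool that made the values with decimals is not given in the sources used here. Between 4.61% and 4.97% of the values in a library were whole to within 0.001. Values between 0.5 and 6 in genes with a single transcript were compared between each pair of libraries. The fullest bin of log2 ratios, 0.05 wide, was centred within 0.05 of 0 in every pair, with 15 to 51 genes against a median of 1 or 2 per bin. A library factor well beyond that width had therefore not been divided out, while a smaller one is not excluded.

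The table had 75959 transcripts, 29883 of them curated and 46076 predicted, under 21878 gene symbols. It had no duplicated transcript, 0 entries without a gene symbol and 0 sample columns without a group. Estimated counts were summed per gene symbol and rounded to whole numbers. Totals were 21578355 for vector, 20783939 and 20496183 for LPS, and 19956044 and 19836203 for LPS with arctigenin. The 13 mitochondrially encoded genes of a prepared list, Cxcl11, Mx1, Mx2 and Hbb-b1 were not found in the table under those symbols and are not analysed here. Genes with near-identical copies, such as Hspa1b with Hspa1a, the ribosomal proteins with their pseudogenes, and the Oas, Gbp, Ccl and H2 families, are uncertain, because the estimation could have divided shared reads between copies. Whether counting used the strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated.

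Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with Benjamini-Hochberg adjustment (estimateDisp, glmQLFit with the robust option, glmQLFTest). The filterByExpr filter used a minimum count of 10 and a minimum total of 15. It kept 11575 genes and left out 10303. TMM factors were 1.16 for vector, 0.981 and 0.972 for LPS, and 0.942 and 0.956 for LPS with arctigenin. CPM values are normalised by TMM. All 5 libraries entered a single fit with group as the only term, which left 2 residual degrees of freedom and a biological coefficient of variation of 7.13%. The lone vector library was assumed to vary like the libraries of the other groups. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples. A gene was called at an adjusted p under 0.05. Standard errors were computed as the size of the log2 fold change over the square root of the F statistic.

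For a gene with 0 counts in vector the fold is given as a lower bound against a floor of 3 counts in that library, equal to 0.139 CPM before TMM scaling. For 1 to 3 counts in the lower group the ratio of counts is given with a 95% counting interval. Intervals and floors cover counting error only. The fitted fold of such a gene depends on the default prior count of the edgeR fit. Log2 CPM values used a prior count of 2.

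The 23 gene lists, the comparisons, the tests, the alternatives other than the length and GC correction and the rule for named genes were written before the data were examined. The rule took, for LPS against vector and for LPS with arctigenin against LPS, the 10 largest rises and 10 largest falls by fitted log2 fold change. These had to have an adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the libraries of both groups, and symbols of unnamed gene models were passed over. It also took up to 4 called members with the largest change in each list, and 8 key genes whatever their result: Tnf, Il1b, Il6, Nos2, Ptgs2, Ccl2, Cxcl10 and Hmox1. Some genes taken by the rule are not used here. The lists were inflammatory cytokines, chemokines, type I interferon response, inducible mediator enzymes, NF-kB pathway and feedback, and immediate early genes with MAPK feedback. Further lists were the NRF2 antioxidant response, chaperones of the endoplasmic reticulum with the unfolded protein response, the amino acid stress response driven by ATF4, cytosolic heat shock, glycolysis and hypoxia, and nuclear genes of oxidative phosphorylation. The others were cholesterol synthesis, S phase, mitosis, p53 targets, alternative activation, macrophage identity, antigen presentation, osteoclast genes, markers of other cell types, mitochondrially encoded genes and cytosolic ribosomal proteins. Lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 22 lists with a measured gene. The fry test of limma, which asks whether the genes of a list changed without comparing them to other genes, was run beside it. An adjusted p of a list is from camera unless fry is named.

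Enrichment of genes called with an absolute log2 fold change of at least 1 was tested by a one-sided hypergeometric test on the gene ontology and pathway terms in the deposited table, for terms of 15 to 500 tested genes. The background was the 10032 tested genes with an ontology term of that size or the 4385 with a pathway of that size. Called genes outside the background were left out. Because both main comparisons use the same LPS libraries, 50 sets of unchanged arctigenin libraries were simulated against them. Locations are from the GENCODE vM1 models on build NCBIM37, which is mm9, as were transcript length and GC content, which 10495 of the tested genes (90.7%) had.

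The scripts were tested on simulated counts with planted changes. For LPS against vector, over 11307 genes, edgeR recovered 87 of 100 genes planted at 2-fold and 59 of 100 at 1.5-fold, with 11 unchanged genes called. For LPS with arctigenin against LPS the numbers were 89, 80 and 4. With a list planted at 1.5-fold, camera called it with the preset correlation and missed it with the estimated one, and called 0 of 21 unchanged lists. The alternatives tried were RLE size factors, no filter, a CPM filter, a fold threshold, transcripts in place of genes, DESeq2 1.42.0, limma-voom, each replicated library left out in turn, 4 libraries without vector, and the replicate number as a block. A correction for transcript length and GC content was added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.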

Results

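Gene expression was measured by RNA sequencing in 5 libraries of RAW264.7 cells, a mouse macrophage-like line. The series set cells with vector (1 library) beside cells with LPS (2 libraries), the bacterial outer membrane lipid that activates macrophages, and cells with LPS and arctigenin (2 libraries), a plant lignan. Totals per library lay between 19836203 and 21578355 estimated counts. In vector the gene with the most counts was Spp1, osteopontin, with 1.52% of the counts, and in both LPS libraries it was Ptgs2, the inducible cyclooxygenase, with 1.33% and 1.39%. Across genes, log2 CPM of the LPS replicates correlated at r = 0.989 and that of the LPS with arctigenin replicates at r = 0.986, against 0.929 to 0.930 between vector and LPS. Differences between replicates exceeded counting noise, with a chi-square per degree of freedom of 5.13 for LPS and 8.30 for LPS with arctigenin. The first principal component, with 57.5% of the variance, set vector apart from the other libraries, and the second, with 28.8%, set LPS apart from LPS with arctigenin.

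LPS against vector describes the activation on which arctigenin was tested. Nos2, which makes nitric oxide, rose 45.8-fold, from 14.98 CPM in vector to 686 ± 27.5 CPM (SD, n = 2) with LPS. Il6, a fever-inducing cytokine, rose 48.9-fold, from 1.83 to 89.9 ± 10.9 CPM, and the monocyte attractant Ccl2 rose 13.7-fold, from 37.9 to 518 ± 6.61 CPM. Ptgs2 rose 10.4-fold, from 1335 to 13926 ± 515 CPM, and Cxcl10, an interferon-induced chemokine, rose 10.8-fold, from 19.4 to 211 ± 35.4 CPM. Il1b rose 6.17-fold, from 78.4 to 484 ± 6.27 CPM, and Hmox1, which degrades heme, rose 5.00-fold, from 112 to 562 ± 20.1 CPM. Of the 8 key genes Tnf rose least, 1.58-fold (log2 0.66 ± 0.12, SE, adjusted p = 0.00169), from 338 to 533 ± 37.5 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3137 genes rose and 2887 fell, 6024 in all of 11575 tested. With 1 vector library, the spread behind these calls came only from the LPS and the LPS with arctigenin replicates. Among these, 1058 rose and 837 fell by at least 1 on the log2 scale. With transcripts in place of genes, 1318 rose and 486 fell, 1804 of 35464 tested.

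**Figure D1:**
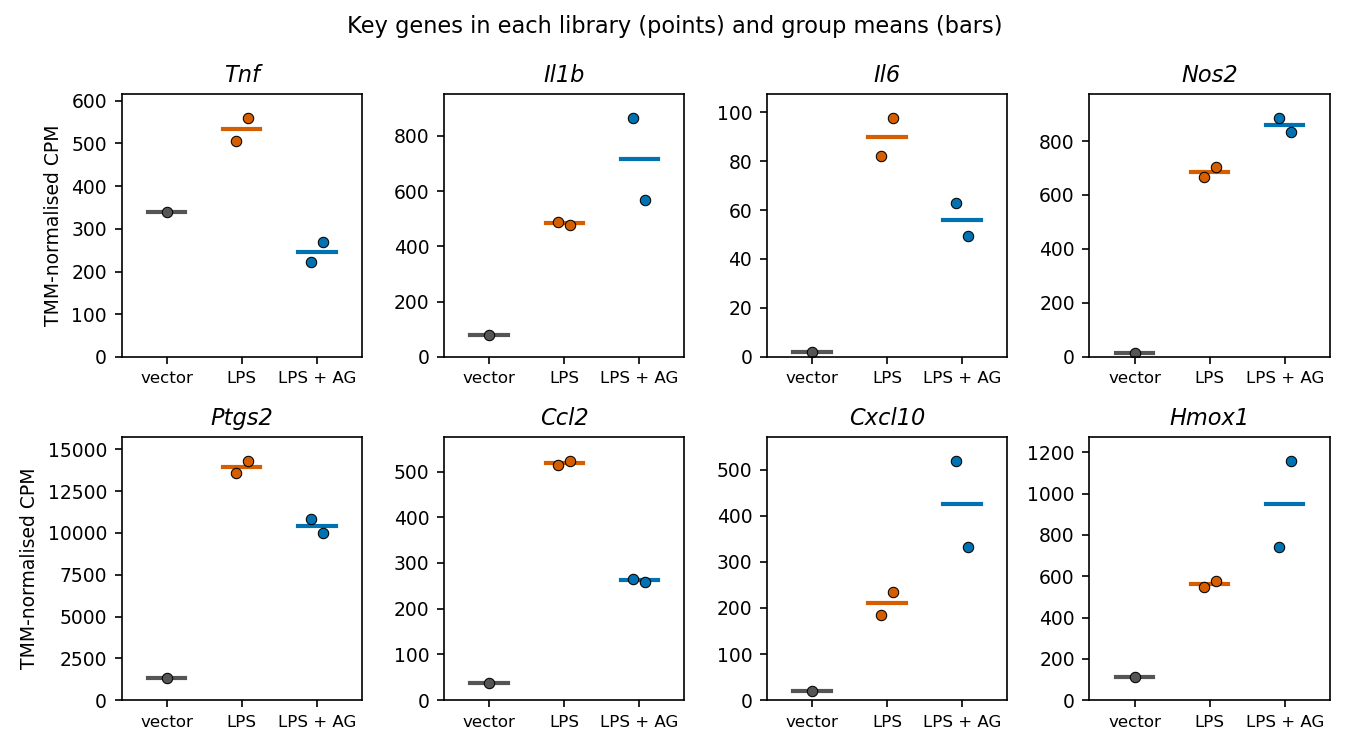
TMM-normalised CPM of the 8 key genes, on a linear axis from 0, in each library (points) of vector, LPS and LPS with arctigenin (AG), with horizontal bars at the group means. Tnf, Il6, Ptgs2 and Ccl2 were lower with arctigenin than with LPS alone, Nos2 was higher, and the arctigenin replicates lay far apart for Il1b, Cxcl10 and Hmox1.

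On build mm9 the gene models of Ccl2 and Nos2 lie on chromosome 11, from 81849073 to 81850955 and from 78734289 to 78773756, both on the plus strand. Il6 lies on chromosome 5 from 30339701 to 30346508 on the plus strand, and Cxcl10 on the same chromosome from 92775664 to 92777915 on the minus strand. Tnf lies on chromosome 17 from 35336326 to 35338952 and Il1b on chromosome 2 from 129190310 to 129196880, both on the minus strand. Ptgs2 lies on chromosome 1 from 151947250 to 151955140 and Hmox1 on chromosome 8 from 77617490 to 77624495, both on the plus strand. The positions of Il1b and Ptgs2 are rounded in their last digit. All 8 genes are annotated as protein-coding.

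The largest rise under LPS was in Il33, an alarmin of the interleukin-1 family, from 1.51 CPM in vector to 1646 ± 24.0 CPM (SD, n = 2), or log2 10.08 ± 0.21 (SE). Timp1, an inhibitor of matrix metalloproteinases, rose 340-fold (log2 8.41 ± 0.39), AA467197 rose 281-fold and the collagen gene Col5a3 rose 150-fold. Other large rises started from almost no counts in vector. The ratio to vector was 536 (95% counting interval 96.0 to 21199.8) for the carbonic anhydrase Car4, 355 (121 to 1722) for the endothelial lipase Lipg, and 207 (36.8 to 8189.5) for Hamp, which encodes hepcidin. It was 177 (31.6 to 7034) for the cytokine Il1f6 and 134 (36.8 to 1109) for the casein gene Csn1s1. Crispld2 had 0 counts in vector and was at least 16.4-fold higher with LPS. The largest falls were in the adhesion molecule Kirrel3, 32.0-fold, Cytip, 13.1-fold, and Rgs2, a regulator of G-protein signalling, 10.4-fold. Acot2 fell 8.57-fold, lymphotoxin beta (Ltb) 7.93-fold, the receptor Gpr84 7.80-fold, Lrr1 7.73-fold, Trmt61a 7.43-fold, Igfbp4 6.76-fold and the thymidine kinase Tk1 6.75-fold. The log2 fold change of Trmt61a, −2.89, was −4.02 without LPS replicate 1 and −2.27 without LPS replicate 2.

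Inflammatory lists rose with LPS. Of 18 inflammatory cytokines 14 rose and 2 fell, including Il10 (45.8-fold) and Csf3 (29.3-fold) among the rises and Il12b, at 0 counts in vector and at least 5.19-fold higher (adjusted p = 0.0218, and 0.0923 without LPS replicate 2). The median log2 fold change was 3.40, or 2.50 with genes at 0 counts in vector set to their bound, and the camera adjusted p was 9.94e-06 (adjusted p = 0.482 with an estimated correlation). Of 15 chemokines 13 rose and 1 fell, with a median of 2.93, or 2.70 with the bound (adjusted p = 1.8e-05, and 0.482 with an estimated correlation). Ccl5 rose 39.9-fold, Ccl7 rose 23.6-fold, and Ccl22, which attracts regulatory T cells, rose 21.3-fold (adjusted p = 0.0113), a call lost without the count filter (0.171) and in limma-voom (0.319). Of 34 type I interferon response genes 33 rose and 0 fell, with a median of 2.02 (adjusted p = 3.23e-15, and 0.482 with an estimated correlation). Gbp5 rose 60.4-fold, Rsad2, the antiviral protein viperin, 31.9-fold, Ifit2 25.8-fold and Ifit3 24.3-fold. Of 18 inducible mediator enzymes 15 rose and 1 fell, with a median of 2.72, or 2.23 with bounds (adjusted p = 1.81e-06, and 0.482 with an estimated correlation). Acod1, which makes itaconate, rose 19.0-fold. The list also held the acute-phase protein Saa3, which rose 75.4-fold, and the arginine transporter Slc7a2, which had 0 counts in vector and was at least 53.5-fold higher.

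Signalling and surface lists also moved. Of 21 NF-kB pathway and feedback genes 13 rose and 4 fell (14 and 5 adjusted over the list alone), with a median of 0.67 and an adjusted p of 0.0198 (0.484 with an estimated correlation). The feedback inhibitors Tnfaip3 (5.28-fold) and Nfkbia (4.19-fold), the ribonuclease Zc3h12a (4.06-fold) and the costimulatory receptor Cd40 (3.64-fold) rose. Of 14 antigen presentation genes 10 rose and 1 fell, with a median of 0.72 and an adjusted p of 0.00474 (0.482 with an estimated correlation). The costimulatory ligands Cd86 and Cd80 rose 7.70-fold and 5.46-fold, and the peptide transport genes Tap1 and Tapbp rose 3.36-fold and 2.79-fold. Of 21 cholesterol synthesis genes 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.38 and an adjusted p of 0.00474 (0.511 with an estimated correlation). Dhcr7, a reductase of the last steps of the pathway, rose 1.86-fold.

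The mitosis and S phase lists were lower with LPS, and less firmly so were the lists of ATF4-driven and nuclear oxidative phosphorylation genes. Of 19 mitosis genes 18 fell and 0 rose, with a median of −0.88 and an adjusted p of 3.24e-06 (0.511 with an estimated correlation). The spindle motor Kif11 fell 3.44-fold, the kinase Aurkb 3.14-fold, the topoisomerase Top2a 2.81-fold and Birc5, survivin, 2.79-fold. Of 18 S phase genes 14 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of −0.85 and an adjusted p of 0.001 (0.482 with an estimated correlation). The replication licensing genes Cdc6 and Mcm7 fell 2.54-fold and 2.52-fold, while the cyclin Ccne1 rose 3.09-fold. Of 18 amino acid stress genes driven by ATF4, 13 fell and 3 rose, with a median of −0.36 and an adjusted p of 0.0383 (0.678 with an estimated correlation, 0.0660 without LPS replicate 1 and 0.0718 without LPS replicate 2). The pseudokinase Trib3 fell 3.89-fold, Atf5 3.37-fold and the serine pathway enzyme Shmt2 2.15-fold, while the mTOR inhibitor Ddit4 rose 3.57-fold. Of 22 nuclear oxidative phosphorylation genes 12 fell and 0 rose, with a median of −0.26 and an adjusted p of 0.0409 (0.511 with an estimated correlation). That call was lost without LPS replicate 1 (0.0659), LPS replicate 2 (0.0890), LPS with arctigenin replicate 1 (0.0509) or 2 (0.0504). Long transcripts were higher with LPS in general, with a median log2 fold change of 0.22 among the longest 2099 genes and −0.18 among the shortest 2099. After a correction for transcript length and GC content the oxidative phosphorylation median was −0.16, and 7 genes were called as lower. Atp5o fell 1.46-fold, Ndufa9 1.40-fold, Atp5c1 1.35-fold and Sdha 1.31-fold.

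The remaining lists were not called as a whole by camera. Of 19 immediate early genes with MAPK feedback 7 rose and 3 fell (adjusted p = 0.11), with the phosphatases Dusp2 up 14.7-fold, Dusp5 7.41-fold and Dusp1 4.63-fold and Ier2 down 2.13-fold. Of 16 NRF2 antioxidant genes 8 rose and 5 fell (adjusted p = 0.161), among them the cystine transporter Slc7a11, up 2.02-fold, Txnrd1, up 1.99-fold, and Gclm, up 1.95-fold. Of 13 heat shock genes 8 rose and 1 fell (adjusted p = 0.139), with the chaperones Hspa1b up 11.1-fold from 0.279 CPM (log2 3.47, and 3.96 and 2.75 without LPS replicate 1 and 2), Hspa4l 2.23-fold, Hspa8 1.66-fold and Hsph1 1.62-fold. Of 20 glycolysis and hypoxia genes 8 rose and 6 fell (8 and 7 adjusted over the list alone). Their median was −0.02 while the mean was 0.10 and the test pointed up (adjusted p = 0.702), and the median was 0.10 after the length and GC correction. The glucose transporter Slc2a1 rose 3.70-fold and the hexokinases Hk1 and Hk2 rose 2.36-fold and 2.27-fold, while Pdk1, which inhibits pyruvate dehydrogenase, fell 3.07-fold. Of 18 endoplasmic reticulum genes 2 rose and 5 fell (median −0.01, adjusted p = 0.565). Herpud1 fell 3.03-fold, Ddit3 1.96-fold, Edem1 1.44-fold, and Sdf2l1 1.38-fold (adjusted p = 0.0126, and 0.0937 without LPS replicate 2). Of 14 p53 targets 4 rose and 4 fell (adjusted p = 0.988), with the death genes Bbc3 down 2.65-fold and Fas up 2.55-fold, Gadd45a down 1.78-fold and Mdm2 up 1.72-fold.

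Of 20 macrophage identity genes 12 rose and 5 fell (median 0.54, adjusted p = 0.062). The receptor Csf1r, on which macrophage survival depends, fell 4.60-fold, while the scavenger receptor Msr1 rose 2.91-fold and the Fc receptor Fcgr1 2.68-fold. Of 11 alternative activation genes 3 rose and 2 fell (adjusted p = 0.319), with the mannose receptor Mrc1 up 31.8-fold, Il4ra up 11.4-fold, Clec10a down 4.68-fold and Klf4 down 2.27-fold. Of 7 osteoclast genes 2 rose and 1 fell (adjusted p = 0.221), with the phosphatase Acp5 up 2.66-fold, Tnfrsf11a up 2.08-fold and the fusion gene Dcstamp down 2.71-fold. Of 6 markers of other cell types 3 rose and 0 fell (adjusted p = 0.221), all at low levels. The fibroblast matrix gene Dcn rose 11.2-fold to 3.62 ± 0.361 CPM (SD, n = 2). Lum had a ratio of 23.7 (95% counting interval 4.00 to 959) and the endothelial gene Pecam1 rose 4.38-fold to 0.892 ± 0.126 CPM. The Lum call (adjusted p = 0.0178) was lost in DESeq2 (0.0629) and without LPS replicate 1 (0.0943) or 2 (0.0590). The Pecam1 call (0.0301) was lost in DESeq2 (0.0968), limma-voom (0.0586) and without LPS replicate 1 (0.0998) or 2 (0.0633). Of 31 cytosolic ribosomal protein genes 1 rose and 8 fell (0 and 0 adjusted over the list alone, adjusted p = 0.143 for the list), with Rpl3 down 1.24-fold, and 3 rose and 1 fell after a correction for transcript length and GC content. The calls of Rps6, up 1.37-fold (adjusted p = 0.0193), and Rpl10a, down 1.20-fold (0.0113), were each lost in some alternatives. The adjusted p was 0.107 for Rps6 in DESeq2 and 0.109 without LPS replicate 2. For Rpl10a it was 0.0916 without LPS replicate 1 and 0.0947 after the length and GC correction. For the lists where no second count is given, the count adjusted over the list alone was the same. The mitochondrially encoded genes are not analysed here.

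In the enrichment test on genes at least 2-fold higher with LPS, inflammatory response (68 of 206 genes, 19.4 by share, adjusted p = 1.06e-18) and defense response to virus (49 of 133, 12.5 by share, 2.16e-15) stood among the leading terms. Lower genes were enriched in centromeric chromosome regions (41 of 135, 9.69 by share, 8.51e-13) and in rRNA processing (30 of 129, 9.26 by share, 2.54e-06).

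LPS with arctigenin against LPS asks what arctigenin changed in activated cells. No solvent control for arctigenin is identified here, so an effect of its solvent cannot be told apart. The inflammatory genes went both ways. Tnf fell 2.17-fold, from 533 ± 37.5 to 246 ± 34.3 CPM (SD, n = 2; log2 −1.12 ± 0.10, SE), and Ccl2 fell 1.97-fold, from 518 ± 6.61 to 262 ± 5.14 CPM (log2 −0.98 ± 0.06). Il6 fell 1.60-fold to 56.1 ± 9.52 CPM (adjusted p = 0.00273) and Ptgs2 fell 1.34-fold to 10403 ± 606 CPM (adjusted p = 0.000459). Nos2 instead rose 1.25-fold to 860 ± 36.2 CPM (adjusted p = 0.00196). Cxcl10 rose 2.02-fold to 425 ± 132 CPM (adjusted p = 0.0115, and 0.165 without the count filter). Hmox1 rose 1.69-fold to 949.8 ± 294 CPM (adjusted p = 0.0221), a call lost without the count filter (0.202), in DESeq2 (0.0511), and without LPS replicate 1 (0.0669) or 2 (0.0515). Il1b rose 1.48-fold to 717 ± 209 CPM (adjusted p = 0.0474), a call lost in 7 of 12 alternatives, among them RLE size factors (0.0527), no count filter (0.276), DESeq2 (0.135) and leaving out LPS replicate 1 (0.104) or 2 (0.117). The log2 fold change of Il1b lay between 0.24 and 0.84 over the alternatives. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2634 genes rose and 2546 fell, 5180 in all, of which 410 rose and 494 fell by at least 1 on the log2 scale. The count was 3234 without LPS replicate 1, and with transcripts in place of genes it was 423 of 35464 tested, 215 higher and 208 lower.

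The largest fall was in Edn1, the vasoconstrictor endothelin-1, 23.2-fold, from 36.4 ± 2.13 to 1.56 ± 0.198 CPM (SD, n = 2), against 0.717 CPM in vector. Egr1, an immediate early transcription factor, fell 12.1-fold, from 77.8 ± 2.66 to 6.44 ± 0.0691 CPM, against 56.5 CPM in vector. Rin1, a regulator of Ras signalling, fell 6.36-fold, Slc46a3 6.07-fold, the growth factor Csf2 5.72-fold, Trim2 5.19-fold, the lysosomal glycoprotein Gpnmb 5.19-fold, Yipf7 5.15-fold, the water channel Aqp9 4.95-fold and the receptor Il7r 4.74-fold. Crispld2 rose 15.3-fold, from 1.96 ± 0.283 to 30.01 ± 7.02 CPM, and Ccl22 rose 13.1-fold, from 9.48 ± 0.157 to 124 ± 63.0 CPM. Bzrap1 rose 9.01-fold, the kinase Dmpk 8.59-fold and the stress-induced chaperone Hspa1b 5.79-fold. The mitotic kinase Plk1 rose 5.08-fold, from 9.65 ± 0.546 to 49.1 ± 5.69 CPM. Akap12 rose 5.07-fold, the helicase Pif1 4.98-fold, Iqgap3 4.80-fold and the spindle gene Troap 4.75-fold. Leaving out a library moved some of these log2 values. Without LPS with arctigenin replicate 1 and 2, Rin1 went from −2.67 to −3.30 and −2.23, Ccl22 from 3.71 to 3.07 and 4.15, and Aqp9 from −2.31 to −1.85 and −2.98. Hspa1b went from 2.53 to 2.05 and 3.25 without LPS replicate 1 and 2.

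Cell cycle genes rose with arctigenin. All 19 mitosis genes rose, with a median of 1.63 and an adjusted p of 2.54e-11 (0.505 with an estimated correlation). The cyclin Ccna2 rose 4.66-fold, the kinetochore gene Cenpf 3.85-fold and Aurkb 3.82-fold. Of 18 S phase genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.94 and an adjusted p of 1.01e-06 (0.438 with an estimated correlation). The cyclin Ccne2 rose 2.78-fold, Cdc6 2.69-fold, the ribonucleotide reductase subunit Rrm1 2.36-fold and the helicase subunit Mcm5 2.34-fold. Among genes at least 2-fold higher, cell division had 67 of 336 genes, against 12.4 by share (adjusted p = 4.6e-28), and the cell cycle pathway had 25 of 114, against 4.32 by share (7.34e-11). Among genes at least 2-fold lower, hematopoietic cell lineage had 15 of 48, against 1.88 by share (4.27e-08), cytokine-cytokine receptor interaction 20 of 129, against 5.06 (1.19e-05), and inflammatory response 24 of 206, against 7.80 (0.000316). Of 14 p53 targets 3 rose and 5 fell (4 and 5 adjusted over the list alone), with a median of 0.02, a mean of −0.19 and a test pointing down (adjusted p = 0.872). The kinase Plk2 fell 3.20-fold, Gadd45a 2.66-fold and Fas 1.80-fold, while the cell cycle inhibitor Cdkn1a rose 1.90-fold. In the enrichment test, the annotated p53 signaling pathway was called among genes at least 2-fold higher, with 9 of 57 against 2.16 by share (adjusted p = 0.0112).

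**Figure D2:**
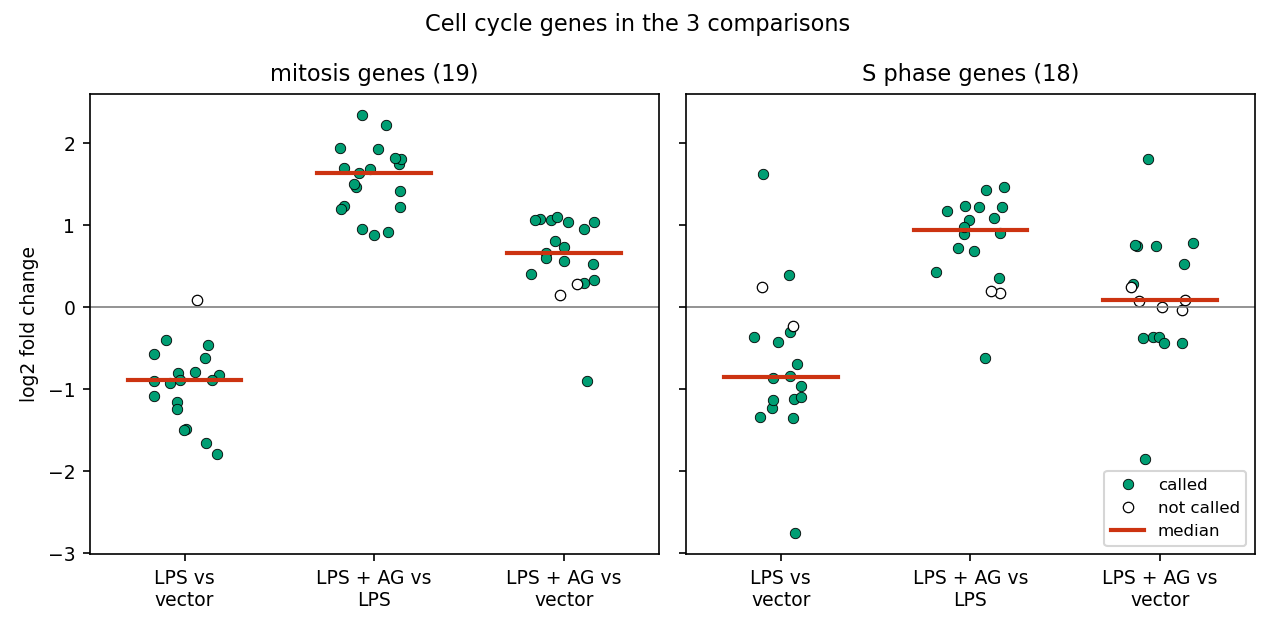
Log2 fold changes (vertical axis) of the 19 mitosis genes and the 18 S phase genes in LPS against vector, LPS with arctigenin (AG) against LPS, and LPS with arctigenin against vector. Each point is a gene, filled where called, and red bars are medians, which for mitosis were −0.88, 1.63 and 0.67.

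The heat shock, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation and ribosomal protein lists rose as well. Of 13 heat shock genes 12 rose and 0 fell, with a median of 0.78 and an adjusted p of 3.95e-06 (0.505 with an estimated correlation). The chaperones Hspa8, Dnajb1 and Dnaja1 rose 2.75-fold, 2.34-fold and 2.14-fold. Of 21 cholesterol synthesis genes 18 rose and 0 fell, with a median of 0.54 and an adjusted p of 9e-07 (0.438 with an estimated correlation). Idi1, an isomerase of the pathway, rose 2.65-fold and the synthase Hmgcs1 rose 2.63-fold. Of 20 glycolysis and hypoxia genes 14 rose and 1 fell, with a median of 0.29 and an adjusted p of 0.000349 (0.438 with an estimated correlation). The glycolytic enzyme gene Pfkl rose 2.15-fold, Bnip3 1.91-fold and the angiogenic factor Vegfa 1.90-fold. Adm rose 1.82-fold (adjusted p = 0.0222, and 0.139 in DESeq2, 0.0577 and 0.141 without LPS replicate 1 and 2, and 0.0616 without LPS with arctigenin replicate 1). Of 22 nuclear oxidative phosphorylation genes 17 rose and 0 fell, with a median of 0.25 and an adjusted p of 8.1e-05 (0.438 with an estimated correlation). Cox7a2 rose 1.84-fold, Ndufa4 1.62-fold, Cycs, cytochrome c, 1.33-fold and Cox5b 1.38-fold. Of 31 ribosomal protein genes 30 rose and 0 fell (31 and 0 adjusted over the list alone), with a median of 0.30 and an adjusted p of 8.58e-07 (0.631 with an estimated correlation). Rps2 rose 1.36-fold, and Rpl27 and Rpl11 rose 1.33-fold each. Short transcripts were higher in general, with a median log2 fold change of 0.17 among the shortest 2099 genes and −0.07 among the longest 2099. After a correction for length and GC content, 15 of the 31 ribosomal protein and 11 of the 22 oxidative phosphorylation genes were called as higher, without Rpl27 (adjusted p = 0.703) and Cox5b (0.292).

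Immediate early and NF-kB genes fell. Of 19 immediate early genes with MAPK feedback 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −0.55 and an adjusted p of 0.000679 (0.438 with an estimated correlation). The phosphatase Dusp6, a feedback inhibitor of ERK, fell 3.73-fold, Ier2 3.28-fold and Junb 2.33-fold. Of 21 NF-kB pathway and feedback genes 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −0.36 and an adjusted p of 0.000446 (0.438 with an estimated correlation). Tnfaip3 fell 2.22-fold, Tnfaip2 2.01-fold, the signalling inhibitor Irak3 1.89-fold and Nfkbiz 1.82-fold.

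Cytokine, chemokine and interferon lists were split. Of 18 inflammatory cytokines 9 fell and 4 rose (9 and 5 adjusted over the list alone; median −0.43, adjusted p = 0.198 by camera and 0.00238 by fry). Csf1, the macrophage growth factor, fell 4.02-fold and Il10, an anti-inflammatory cytokine, fell 3.08-fold, from 168 ± 4.25 to 54.5 ± 0.966 CPM (SD, n = 2). Of 15 chemokines 8 fell and 5 rose (8 and 6 adjusted over the list alone), with a median of −0.33 but a mean of 0.36 and a test pointing down (adjusted p = 0.503). Ccl5 rose 3.04-fold, from 134 ± 21.01 to 406 ± 80.1 CPM. Cxcl9 rose 2.82-fold (adjusted p = 0.0146, and 0.0699 in DESeq2, 0.0865 and 0.0887 without LPS replicate 1 and 2, and 0.106 without LPS with arctigenin replicate 1). Ccl12 rose 3.22-fold (adjusted p = 0.0313, and 0.109 in DESeq2, 0.197 and 0.0681 without LPS replicate 1 and 2, 0.138 without LPS with arctigenin replicate 2, and 0.0619 after the length and GC correction). Of 34 interferon response genes 11 rose and 12 fell (12 and 12 adjusted over the list alone), with a median of 0.02, a mean of −0.03 and a test pointing down (adjusted p = 0.872). Rsad2 fell 2.37-fold and Cmpk2 1.53-fold. Oasl1 rose 1.85-fold and Isg20 rose 1.65-fold (adjusted p = 0.0093, and 0.0659 without LPS with arctigenin replicate 1). Of 18 mediator enzymes 5 rose and 8 fell, with a median of −0.12 (0.01 after the length and GC correction), a mean of 0.02 and a test pointing down (adjusted p = 0.58). Ass1, which regenerates arginine, rose 2.71-fold and Saa3 fell 1.91-fold. Slc7a2 fell 2.56-fold (adjusted p = 0.0227, and 0.119 and 0.0865 without LPS replicate 1 and 2), and its log2 fold change of −1.36 was −2.27 without LPS with arctigenin replicate 1 and −0.80 without replicate 2. Arg1, which degrades arginine, rose 6.69-fold to 1.03 ± 0.0305 CPM (adjusted p = 0.0277). That call was lost in DESeq2 (0.105) and without LPS replicate 1 (0.183), LPS replicate 2 (0.0557), LPS with arctigenin replicate 1 (0.0613) or 2 (0.0590). With few counts under LPS, its log2 fold change of 2.74 was 2.02 without LPS replicate 1 and 4.24 without LPS replicate 2.

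**Figure D3:**
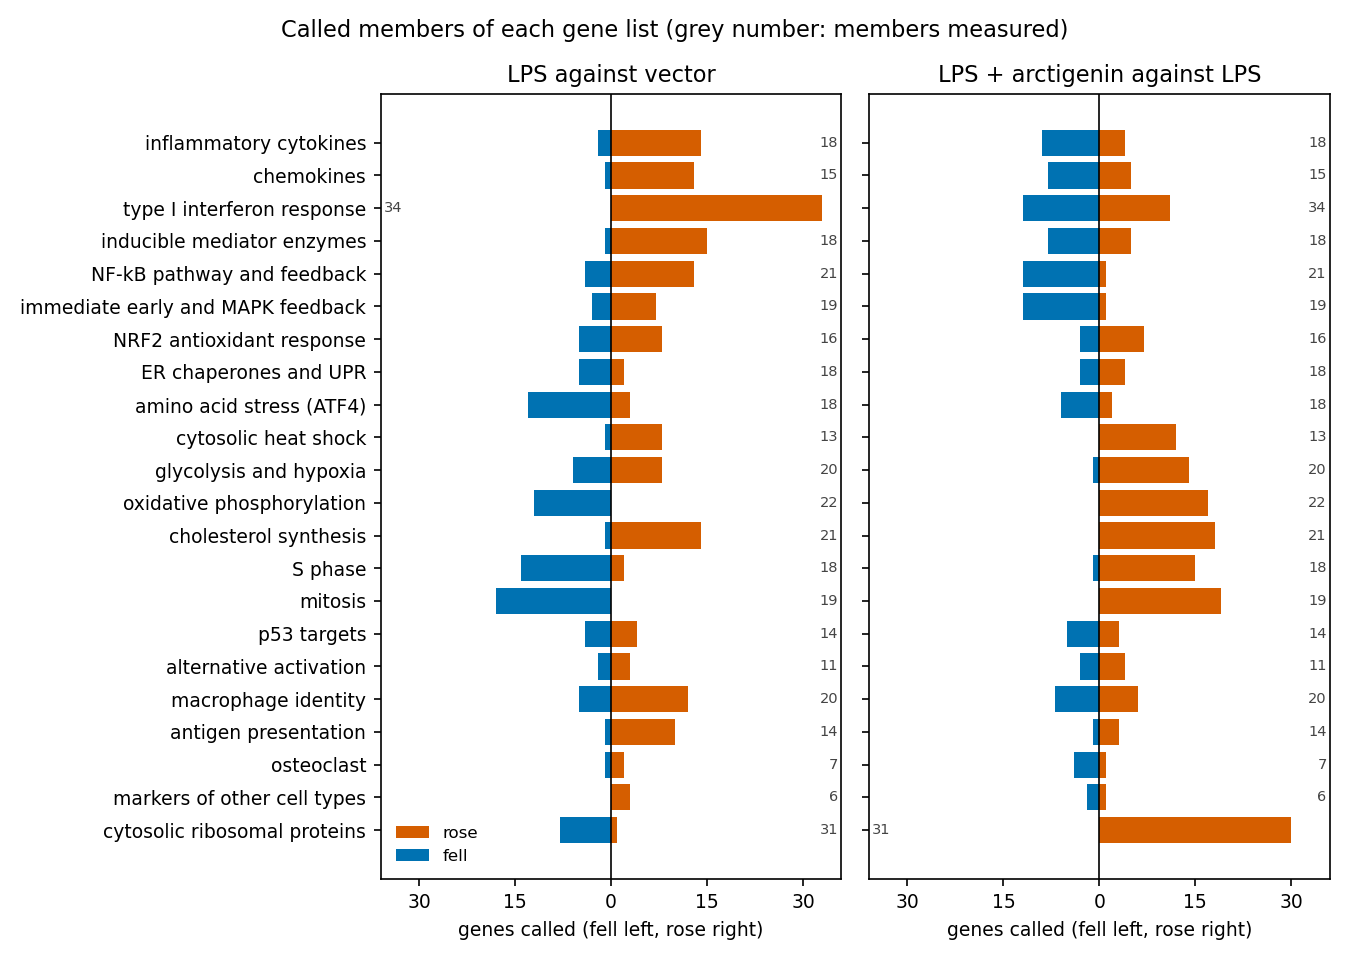
Numbers of genes (horizontal axis) that rose (orange, right) and fell (blue, left) in each list for LPS against vector and LPS with arctigenin against LPS, with the number measured in grey. With arctigenin all 19 mitosis genes and 30 of 31 ribosomal protein genes rose, while 12 NF-kB genes and 12 immediate early genes fell. After the length and GC correction 15 of the 31 ribosomal protein genes were called as higher.

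Identity and presentation lists had no call as a whole by camera. Of 20 macrophage identity genes 6 rose and 7 fell, with a median of −0.05, a mean of 0.10 and a test pointing down (adjusted p = 0.777). The fractalkine receptor Cx3cr1 rose 2.43-fold, the LPS co-receptor Cd14 rose 2.12-fold and the protease Ctsd fell 1.46-fold. Mertk, a receptor for dying cells, rose 4.09-fold (adjusted p = 0.0293), a call lost in DESeq2 (0.0926) and without LPS replicate 1 (0.190), LPS replicate 2 (0.0659) or LPS with arctigenin replicate 1 (0.124). Its log2 fold change of 2.03 was 1.56 without LPS replicate 1 and 2.71 without LPS replicate 2. Of 11 alternative activation genes 4 rose and 3 fell (median 0.09, adjusted p = 0.777). Mrc1 rose 3.14-fold and Klf4 fell 2.19-fold. Socs2 fell 5.71-fold (adjusted p = 0.00962, and 0.0899 without LPS replicate 2). Ccl24, an eosinophil attractant, had a ratio of 11.4 (95% counting interval 3.56 to 58.1), and its call (adjusted p = 0.0268) was lost in DESeq2 (0.0797) and without LPS replicate 1 (0.162) or LPS with arctigenin replicate 1 (0.0509) or 2 (0.0579). The fitted log2 value of Ccl24, 3.40, was 2.45 without LPS replicate 1 and 7.15 without LPS replicate 2, where no LPS count was left. Of 14 antigen presentation genes 3 rose and 1 fell, with a median of 0.08, a mean of −0.03 and a test pointing up (adjusted p = 0.777). Cd80 fell 2.77-fold, and the invariant chain Cd74 rose 1.41-fold. Psmb10 rose 1.29-fold (adjusted p = 0.0196, 0.145 in DESeq2, and 0.0856 and 0.107 without LPS replicate 1 and 2), and H2-K1 rose 1.20-fold (0.0042, and 0.0525 without LPS replicate 2). Of 7 osteoclast genes 1 rose and 4 fell (median −0.56, adjusted p = 0.169). Atp6v0d2, a subunit of the proton pump, fell 14.97-fold, from 4.84 ± 0.747 to 0.318 ± 0.00214 CPM (SD, n = 2), Dcstamp fell 1.64-fold and Ocstamp rose 3.22-fold. Acp5 fell 1.48-fold (adjusted p = 0.0341), a call lost in DESeq2 (0.180) and without LPS replicate 1 (0.181), LPS replicate 2 (0.0893) or LPS with arctigenin replicate 1 (0.115).

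Of 16 NRF2 antioxidant genes 7 rose and 3 fell (median 0.19, adjusted p = 0.546). The peroxiredoxin Prdx1 rose 1.69-fold and Pgd 1.47-fold, while the autophagy receptor Sqstm1 fell 2.15-fold (adjusted p = 0.00251, and 0.0521 without the count filter). Of 18 endoplasmic reticulum genes 4 rose and 3 fell, with a median of 0.04, a mean of −0.02 and a test pointing up (adjusted p = 0.777). Ddit3 fell 1.86-fold and Herpud1 fell 1.48-fold (adjusted p = 0.00572, and 0.0622 without LPS replicate 1), while the chaperones Manf and Calr rose 1.29-fold and 1.27-fold. Of 18 ATF4-driven genes 2 rose and 6 fell (median −0.10, adjusted p = 0.198, and 0.0208 without LPS with arctigenin replicate 2). Chac1 fell 1.80-fold, the asparagine synthetase Asns fell 1.48-fold, Nupr1 rose 1.51-fold and Trib3 fell 2.39-fold (adjusted p = 0.00679, and 0.0979 without the count filter). Of 6 markers of other cell types 1 rose and 2 fell, with a median of 0.12, a mean of −0.51 and a test pointing down (adjusted p = 0.777). Dcn fell 7.94-fold, to 0.450 ± 0.0344 CPM (SD, n = 2). The Lum fall of 4.95-fold (adjusted p = 0.0431) was lost without the count filter (0.0626), in DESeq2 (0.160), and without LPS replicate 1 (0.224), LPS replicate 2 (0.124) or LPS with arctigenin replicate 1 (0.165), and its log2 value of −2.31 was −1.81 and −3.07 without LPS with arctigenin replicate 1 and 2. The Pecam1 rise of 2.81-fold (adjusted p = 0.0194) was lost in DESeq2 (0.0976) and without any library: LPS replicate 1 (0.0825), LPS replicate 2 (0.122), LPS with arctigenin replicate 1 (0.0655) or 2 (0.0504). For the lists where no second count is given, the count adjusted over the list alone was the same.

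LPS with arctigenin against vector shows where the treated cells stood relative to cells with vector. Interferon response genes were still high, with 33 of 34 higher and a median of 1.86 (adjusted p = 1.01e-12, and 0.484 with an estimated correlation), as were inflammatory cytokines, with 14 of 18 higher and 3 lower (median 2.99, or 2.62 with genes at 0 counts in vector set to their bound, adjusted p = 0.000349, and 0.418 with an estimated correlation). Of the mitosis genes 16 rose above vector and 1 fell (median 0.67, adjusted p = 0.00114, and 0.75 with an estimated correlation). Of the S phase genes 7 rose and 6 fell (median 0.09, adjusted p = 0.819). Cholesterol synthesis genes were higher than in vector as well, 19 of 21 (median 0.91, adjusted p = 3.66e-06, and 0.418 with an estimated correlation), and 12 of 13 heat shock genes were higher (median 1.12, adjusted p = 0.000168, and 0.625 with an estimated correlation). Of the ATF4-driven genes 15 fell and 3 rose (median −0.64, adjusted p = 0.0069, and 0.75 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3524 genes rose and 2979 fell, 6503 in all, and with transcripts in place of genes 1673 rose and 802 fell, 2475 in all. The calls in this comparison also contain no spread between vector libraries.

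The effects of LPS and of arctigenin were set side by side. Of the genes called in both comparisons 2033 changed in opposite directions and 1183 in the same direction, so 63.2% were opposed. Across all tested genes the arctigenin libraries did not lie closer to vector. Their log2 CPM correlated with vector at r = 0.915 and 0.922, against 0.930 and 0.929 for LPS. Plk1, Ccna2 and Aurkb fell with LPS and rose with arctigenin, Ccl2 and Il10 rose with LPS and fell with arctigenin, and Ccl5 and Mrc1 rose in both. There were 1013 genes higher with LPS and lower with arctigenin, where independent lists would share 690.0, and 1020 lower with LPS and higher with arctigenin, where they would share 657. The genes higher in both numbered 636 against 714, and those lower in both 547 against 635. Across the 11575 genes, which are not independent replicates, the log2 fold changes had r = −0.174 and rho = −0.161. In 50 simulated sets of unchanged arctigenin libraries the mean r was −0.124 and the mean rho −0.107. The simulated arctigenin fold changes held noise only, so these means do not give the part of the observed correlation due to shared libraries. Correlation is scaled by the spread of the fold changes, and covariance is not. The covariance was −0.112 against a simulated −0.0326 (−0.0395 to −0.0244), a difference of −0.0794. With separate LPS libraries on each side it was −0.0785 and −0.0604. The simulated sets had 2.12 genes called with arctigenin on average, of which 1.24 were opposed and 0.18 went the same way, too few to compare with the observed share. Both comparisons use the same 2 LPS libraries, so part of the excess over independent lists may come from those shared controls. The count of opposed genes was 1178 without LPS replicate 1 and 1274 without LPS replicate 2.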

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

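The length and GC correction was the only alternative chosen after seeing the data. No named gene changed sign under any alternative computed per gene. RLE size factors, both other filters, limma-voom, DESeq2 (4603, 3914 and 5083 genes in the 3 comparisons) and the length and GC correction (5486, 4758 and 5924) stayed within 1.5 times the counts in the report. That correction covers only the 10495 genes with length and GC. Among these, LPS calls went from 2900 higher and 2642 lower to 2554 and 2932. With an absolute log2 fold change of at least 1 the counts were 1895 for LPS against vector, 904 for LPS with arctigenin against LPS and 2334 for LPS with arctigenin against vector, fewer because the threshold is stricter. With transcripts in place of genes, over 35464 transcripts, they were 1804 (73.1% higher, against 52.1% of genes), 423 and 2475, and the cause was not tested. Leaving out each replicated library in turn gave 4543 to 6574, 3234 to 5180 and 5881 to 6472 genes, and 1178 to 2118 opposed genes. Each such fit leaves a group with 1 library, assumed to vary like the others. DESeq2 gave 1426 opposed genes. Without the vector library 5270 genes differed between LPS with arctigenin and LPS. The replicate numbers are shared by 2 pairs with no label of a shared day, and deviations of same-numbered libraries had r = −0.008. Using the number as a replicate block gave 5320 genes, and of the named genes it ended the call of Cxcl10 (adjusted p = 0.0906). Of the named genes, 12 calls of the arctigenin comparison were lost in DESeq2, 14 without LPS replicate 1 and 14 without LPS replicate 2. Besides the glycolysis list under LPS and the mediator enzymes with arctigenin, the length and GC correction turned the sign of the median of the p53 targets with arctigenin, from 0.02 to −0.0055. With an estimated correlation, 0 lists were called in the LPS or the arctigenin comparison, where 11 and 9 were called with the preset one. With arctigenin fry called 4 lists that camera did not. The adjusted p by fry was 0.00238 for inflammatory cytokines and for osteoclast genes, 0.0344 for chemokines and 0.0427 for endoplasmic reticulum genes. With LPS fry also called the immediate early, glycolysis and hypoxia, macrophage identity, alternative activation, osteoclast and other cell type lists. It did not call the ATF4-driven list. The remaining lists had the same call by fry and camera. No alternative prior count was tried.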

Other observations

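The tests of library scaling for the mitosis and lysosome genes, of length and GC content for the mitosis genes and of cell cycle phase were chosen only after the result was seen, as were the camera test over pathways and the choice of the lysosome pathway. Lysosome genes were lower with arctigenin. Of 114 tested genes of the lysosome pathway annotated with the deposited counts, 66 fell and 11 rose against LPS, with a median log2 fold change of −0.36 (adjusted p = 2.98e-05 over 277 pathways, and 0.617 with an estimated correlation). The glycosidase Manba fell by 1.31 ± 0.11 (SE), the cholesterol exporter Npc1 by 0.91 ± 0.08, the sphingolipid activator Psap by 0.89 ± 0.06, the thioesterase Ppt1 by 0.88 ± 0.06 and the protease Lgmn by 0.81 ± 0.07 on the log2 scale. Against vector, LPS alone had raised 50 of the genes and lowered 15 (adjusted p = 0.0161, and 0.375 with an estimated correlation). Of the falls named here, Npc1, Psap and Lgmn were in genes that LPS had raised, by 0.81, 1.43 and 1.11. Manba and Ppt1 were not called under LPS. Pathways that stood higher with arctigenin included the spliceosome, with 80 of 123 genes up and 6 down (median 0.37, adjusted p = 6.44e-09, and 0.617 with an estimated correlation), and DNA replication, with 28 of 35 up and 1 down (median 0.68, adjusted p = 1.88e-07, and 0.617 with an estimated correlation). Most of these changes were under 2-fold, and the enrichment test on genes changed at least 2-fold called none of these pathways. It counted 7 of 114 lower lysosome genes (adjusted p = 0.829), 10 of 123 higher spliceosome genes (0.368) and 5 of 35 higher DNA replication genes (0.262).

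The lysosome median differed by −0.39 from that of random lists matched on expression (95% of random medians lay between −0.06 and 0.13). The pathway had been chosen by a test against other genes in the same data, so this comparison repeats that choice. It gives no separate evidence on a shift in library scaling. Length and GC content were excluded as the whole cause, since the median was −0.33 after their trend was removed and 63 genes were called as lower. The median of the 64 genes not called as higher under LPS differed by −0.40 from that of matched genes. Some of them may have risen without a call, and the matching left out the LPS change, so this difference does not settle a reversal. Of the genes called as lower under LPS, Dnase2a, Galc, Ctns, Sgsh, Gga2, Arsg and Ap4b1 also fell with arctigenin. Among these genes called as lower, Arsb, Nagpa and Man2b1 rose with arctigenin and the rest were not called. A fall in both comparisons is not a reversal of a rise. That arctigenin lowers the lysosome program beyond undoing the LPS response may be taken up as a hypothesis, found and tested on the same data.

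For the rise of mitosis genes with arctigenin, the median lay 1.61 above that of matched random lists. The list had already been called against other genes, so this gives no separate evidence on library scaling. Length and GC content were excluded as the whole cause of the mitosis rise, since the corrected median was 1.64 and all 19 genes were called. The test of cell cycle phase assumed that a larger share of cells in G2 or mitosis alone would leave the S phase list unchanged. That premise was not tested. From LPS to LPS with arctigenin the S phase list rose. Transcript levels do not measure the share of cells in a phase, so a larger share in G2 or mitosis alone was not excluded. The S phase median of 0.94 lay 0.94 above that of matched lists (95% of random medians lay between −0.24 and 0.23), and 15 of 18 genes rose. Against vector, the mitosis median of 0.67 lay above the random range (−0.20 to 0.43) while the S phase median of 0.09 lay inside it (−0.37 to 0.34), with 7 genes up and 6 down, so whether only G2 or mitosis exceeded vector stays open. That arctigenin raises the share of cycling cells relative to LPS may be taken up as a hypothesis, found and tested on the same data.

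The rise of ribosomal protein and nuclear oxidative phosphorylation genes with arctigenin could come in part from transcript length. Against random lists matched on length and expression the ribosomal protein median lay only 0.10 higher (0.30, with 95% of random medians between 0.07 and 0.37), and the oxidative phosphorylation median 0.11 higher (0.25, between −0.04 and 0.34). The length and GC correction took the medians to 0.13 and 0.18, with 15 of 31 and 11 of 22 genes called as higher, so a rise beyond the trend stays open. Whether the trend reflects RNA quality, library preparation or the cells was not tested.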
